A study of Mus musculus with 24 samples.

How the data were processed

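The data are 4C libraries of 2 mouse embryonic stem cell lines, 3 viewpoints and 2 days with 2 biological replicates per group, 24 libraries in 12 groups. Per the labels' protocols, cells were crosslinked with formaldehyde, nuclei were digested with HindIII and ligated, and products were sequenced on a MiSeq. Per the submitters' processing notes, reads were aligned with Bowtie to mm9; the version, the counting step and its filters are not given in the sources used here. The labels call the replicates biological but do not say whether the 3 viewpoints of a line, day and replicate number share a 4C template.

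The authors deposited raw read counts per HindIII fragment of the viewpoint chromosome, 42400 fragments on chromosome 4, 31865 on chromosome 11 and 25150 on chromosome 17, with lists of fragment positions from which the counts were placed in order. Counts are not corrected for PCR duplicates, so intervals and floors cover counting error only. The authors also deposited tables of their own day comparison for viewpoint 154.9 and the wild-type Oct4 allele, whose columns per the file headers hold a mean normalised signal, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. The log2 fold change in the authors' tables is day 0 over day 3, found from the counts, and its sign was turned here. Entries of the authors' tables are unnamed; they were placed by matching their number and their means to the fragments with a median count of at least 40, less 1 fragment at or beside the viewpoint. For the YY1 line and the wild-type allele, leaving out either of 2 adjoining fragments matched about equally well (correlations of 0.9308 and 0.9314).

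Each viewpoint was placed at the fragment with the highest pooled count over the libraries of its table, with no use of groups, because no label gives its position. That fragment and 1 neighbour on either side were left out of shares by distance and of tests. Coordinates are mm9, 1-based, as deposited. The reference annotation at hand is of another build, so no gene is assigned to a fragment and planned lists of fragments over pluripotency and differentiation genes are not reported here.

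Fragments kept by filterByExpr (minimum count 10) were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. The SE given with an edgeR log2 fold change is its absolute value over the square root of the F statistic of the test. It thus follows from the test and is no separate measure of the spread between replicates. Day 3 was compared with day 0 within each line and viewpoint (2 against 2 libraries), and over both lines with line as a covariate. The lines were compared with day as a covariate, and the difference in day effect by an interaction term. DESeq2 1.42.0 was an alternative test. Day effects were correlated between lines by Spearman's rho with 1000 resamples of 1 Mb blocks. Shares of counts in 5 distance bands and the decay slope were compared by an exact two-sided permutation of day labels within tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

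Groups, tests, alternatives and the rule for named fragments were fixed before the data were examined. The rule took, per comparison, the 5 largest rises and 5 largest falls among fragments past the threshold whose libraries did not overlap between groups. For the interaction tests no such separation of libraries was required. Where fewer than 5 passed, the 3 with the smallest p were added as not passing. Fragments within 20 kb of a named one with a smaller p were passed over, and the 5 most contacted fragments per table were also named. The fragment 35671799 to 35674740 was singled out as a call after its values were seen, as were 5089052 to 5089727 and the fragments touching the viewpoints. A fold against a group at 0 is a lower bound computed with 3 counts over the group. It covers counting error in the pooled counts only and not the spread between replicates, so it is no lower bound on a day or line effect. Tests on the fragments touching the viewpoints, on the share held by the viewpoint, without the 4 shallow libraries and with viewpoints as 1 unit were added after seeing the data.

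The edgeR tests were tried on simulated data drawn from the fitted means and dispersions. Of fragments changed 4-fold, edgeR recovered between 0% and 4.55% by comparison, and of those changed 16-fold between 0% and 32.6%, with at most 1 false call per comparison. For the day effect in the YY1 line at viewpoint 154.9 (6707 fragments) it recovered 0% at either size. With the dispersion there lowered to 0.05, a simulation added after the low recovery was seen, it recovered 88% and 100% with 14 false calls among 6707 fragments. The permutation test called 4.5% of 200 unchanged simulated sets and 99.5% of sets shifted by 2 SD. These sets held independent normal values for each library, so they do not cover a template shared by the viewpoints. At the fitted dispersions most changes of up to 16-fold were thus missed in each comparison.

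Alternatives were DESeq2's size factors or totals in edgeR, no filter or a median count of 40, leaving out 50 kb or nothing at the viewpoint, 100 kb windows, a loess trend on distance, replicate number as a block, and each library left out in turn. For shares by distance they were counts capped at the 99th percentile and fragments with a count in place of counts.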

Results

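Chromosomal contacts of 3 viewpoints were measured in mouse embryonic stem cells by paired-end 4C sequencing, a method that counts the DNA fragments ligated to one chosen fragment after crosslinking and HindIII digestion. The viewpoints were a region called 154.9 on chromosome 4, the wild-type Oct4 allele on chromosome 17 and a mutated Oct4 allele on chromosome 11. The Oct4 viewpoints lie on different chromosomes and so are not alleles of one locus. Allele is used here only as a name, and the sample titles do not say how the mutated sequence came to lie on chromosome 11. Oct4, encoded by Pou5f1, is a transcription factor required for pluripotency. The cells were the lines OCF2ΔOCT4/SOX2 and OCF2ΔYY1, here called the OctSox line and the YY1 line, of strain C57Bl/6 x 129/Sv at passage 7. Each viewpoint was assayed at day 0 and day 3 in both lines with 2 biological replicates per group, which gave 12 groups and 24 libraries. The labels name the mutated allele after its line, Mut_OctSox or Mut_YY1. Comparisons of the lines at this viewpoint thus also compare different mutated alleles. The series title places the experiment at the onset of differentiation, and the labels used here do not name the treatment that separates the days.

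Depth differed between viewpoints by over an order of magnitude. The 8 libraries of viewpoint 154.9 held between 1318028 and 2279333 counts, with a median of 1909421. Those of the mutated Oct4 allele held between 2935 and 260509, and those of the wild-type allele between 16297 and 406507. The shallowest library of each Oct4 group at day 3 was replicate 2, with 3395 and 2935 counts at the mutated allele and 18916 and 16297 at the wild-type allele in the OctSox and YY1 lines. A count of 0 allows a share of up to 0.106% of the counts outside the viewpoint in YY1 day 3 replicate 2 of the mutated allele, and up to 0.00018% in YY1 day 0 replicate 2 of viewpoint 154.9. Within 1 Mb of viewpoint 154.9, between 92.9% and 95.5% of the 336 HindIII fragments had at least 1 count. At the mutated Oct4 allele that share was 20.3% (95% Wilson interval 16.8 to 24.3) in the shallowest library, YY1 day 3 replicate 2, and 92.2% (89.3 to 94.3) in the deepest, YY1 day 0 replicate 1.

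The fragment with the highest pooled count was the same in both lines at each viewpoint. In mm9 coordinates it ran from 154951842 to 154952528 on chromosome 4, from 94813216 to 94826180 on chromosome 11 and from 35633988 to 35641095 on chromosome 17. In the YY1 line its lead over the next fragment was narrow, with 8417 against 7124 pooled counts at the mutated and 24210 against 17544 at the wild-type allele. At YY1 day 0 the wild-type viewpoint fragment held 5862 and 1458 counts, below the 12382 and 2624 of the fragment from 35643155. Contact fell steeply over the range from all 3 positions, but rose between the bins at 3.6 and 7.1 Mb in most libraries of the Oct4 alleles. Most wild-type libraries also rose between the bins at 112 and 224 kb. At viewpoint 154.9, YY1 day 3 replicate 2 rose from 0.0036% to 0.00513% per fragment into the bin at 3.6 Mb. The slope of log10 contact on log10 distance between 20 kb and 20 Mb was -1.07 ± 0.117 (SD, n = 8) for viewpoint 154.9, -1.05 ± 0.0719 (SD, n = 8) for the mutated Oct4 allele and -0.962 ± 0.082 (SD, n = 8) for the wild-type allele. Viewpoint 154.9 had 35.6% ± 10.2 (SD, n = 8) of its counts within 0.1 Mb, against 18.7% ± 4.95 (SD, n = 8) and 23.5% ± 8.93 (SD, n = 8) for the mutated and wild-type alleles. Contacts of the wild-type Oct4 allele within 1 Mb were asymmetric at day 0, when 21.0% ± 5.4 (SD, n = 4) of them lay on the side of lower coordinates. For viewpoint 154.9 that side held 50.7% ± 3.37 (SD, n = 4).

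**Figure D1:**
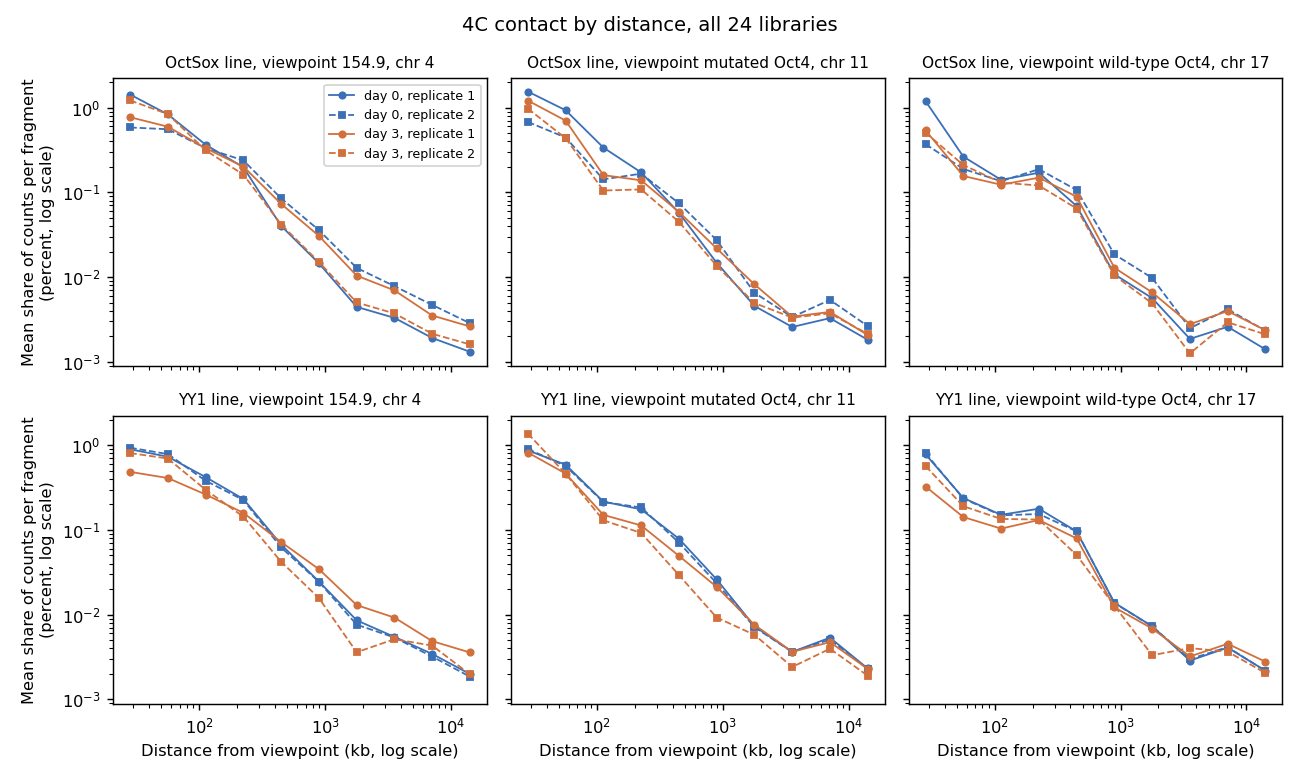
Mean share of counts per HindIII fragment (percent, log scale) against distance from the viewpoint (kb, log scale) in 10 distance bins, one panel per line and viewpoint and one line per library (24 libraries). Contact falls over the whole range in every panel, though not between every pair of bins, mostly in the Oct4 panels. The day 0 and day 3 libraries overlap over much of the range.

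The most contacted regions outside the viewpoints and their direct neighbours lay close by. At the wild-type Oct4 allele, the fragment from 35643155 to 35652106 on chromosome 17 took 8.36% ± 4.63 (SD, n = 4) of the counts in the OctSox line and 5.44% ± 3.21 (SD, n = 4) in the YY1 line. The next was 35671799 to 35674740, 30.7 kb away, with 2.82% ± 1.91 (SD, n = 4) and 2.18% ± 0.794 (SD, n = 4). At the mutated allele, the fragments 94808527 to 94811204 and 94850687 to 94856332 on chromosome 11 had the highest shares over all 4 libraries of a line. In the YY1 line the first ranked there through day 3, with 4.03% and 8.97% of counts outside the viewpoint, against 0.847% and 0.684% at day 0, below the second at 1.89% and 2.13%. In the OctSox line its rank rests on the shallow day 3 replicate 2, with 6.38% against 1.63%, 2.6% and 1.42% in the other 3 libraries. They held 3.01% ± 2.31 and 2.82% ± 1.28 in the OctSox line and 3.63% ± 3.88 and 2.67% ± 1.08 in the YY1 line (SD, n = 4 each). For viewpoint 154.9 the leading fragments differed. The fragment 154914833 to 154926167 on chromosome 4 led in the OctSox line with 3.58% ± 2.42 (SD, n = 4), and 154966015 to 154967572 led in the YY1 line with 2.54% ± 1.63 (SD, n = 4). The YY1 lead rests on day 0, with 2.98% and 4.65% against 1.37% and 1.16% at day 3. At day 3 the fragment 154901822 to 154906277 held 1.32% and 1.82% in that line.

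Far contacts made up a larger part of the profiles at day 3 than at day 0, and contacts at 0.1 to 1 Mb a smaller part. Beyond 20 Mb, viewpoint 154.9 held 12.4% ± 2.18 of its counts at day 0 and 23.3% ± 5.41 at day 3 over both lines (SD, n = 4 each). The mutated Oct4 allele held 17.2% ± 1.85 and 28.4% ± 5.31, and the wild-type allele 14.2% ± 2.37 and 22.7% ± 2.39. In each of the 6 combinations of line and viewpoint both day 3 libraries lay above both day 0 libraries, which chance gives in 1 of 6 arrangements for a single combination. The rise was 4.59, 9.03 and 6.98 percentage points for viewpoint 154.9, the mutated and the wild-type allele in the OctSox line, and 17.1, 13.3 and 9.94 points in the YY1 line. At 0.1 to 1 Mb the shares moved the other way, from 33.3% ± 4.37 to 27.3% ± 4.25 for viewpoint 154.9, from 31.5% ± 1.38 to 20.2% ± 4.65 for the mutated allele and from 31.1% ± 3.48 to 24.9% ± 2.39 for the wild-type allele (SD, n = 4 each).

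The mean change over the 6 combinations was 10.2 percentage points beyond 20 Mb, with a two-sided exact permutation p = 4.3e-05, the smallest that the 46656 arrangements can give, and an adjusted p = 0.000214 over 5 distance bands. At 0.1 to 1 Mb it was -7.81 points (exact permutation p = 0.0006, adjusted p = 0.0015). The bands up to 0.1 Mb, 1 to 5 Mb and 5 to 20 Mb changed by -2.21, -0.359 and 0.22 points, each with an adjusted p = 0.873. The decay slope changed by 0.0523 (exact permutation p = 0.186). These p-values treat the viewpoints of a line as separate experiments. If libraries of one line, day and replicate number came from a single 4C template, only 36 arrangements exist, the smallest possible p is 0.0556, and the exact permutation p-values were 0.0556 beyond 20 Mb and 0.111 at 0.1 to 1 Mb. Both changes also depend on how contacts are counted: with nothing left out at the viewpoint the rise beyond 20 Mb was 4.97 points (adjusted p = 0.0547, exact permutation). With fragments counted in place of counts it was 4.64 points (adjusted p = 0.0494, exact permutation), and the change at 0.1 to 1 Mb turned to 1.0 points.

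**Figure D2:**
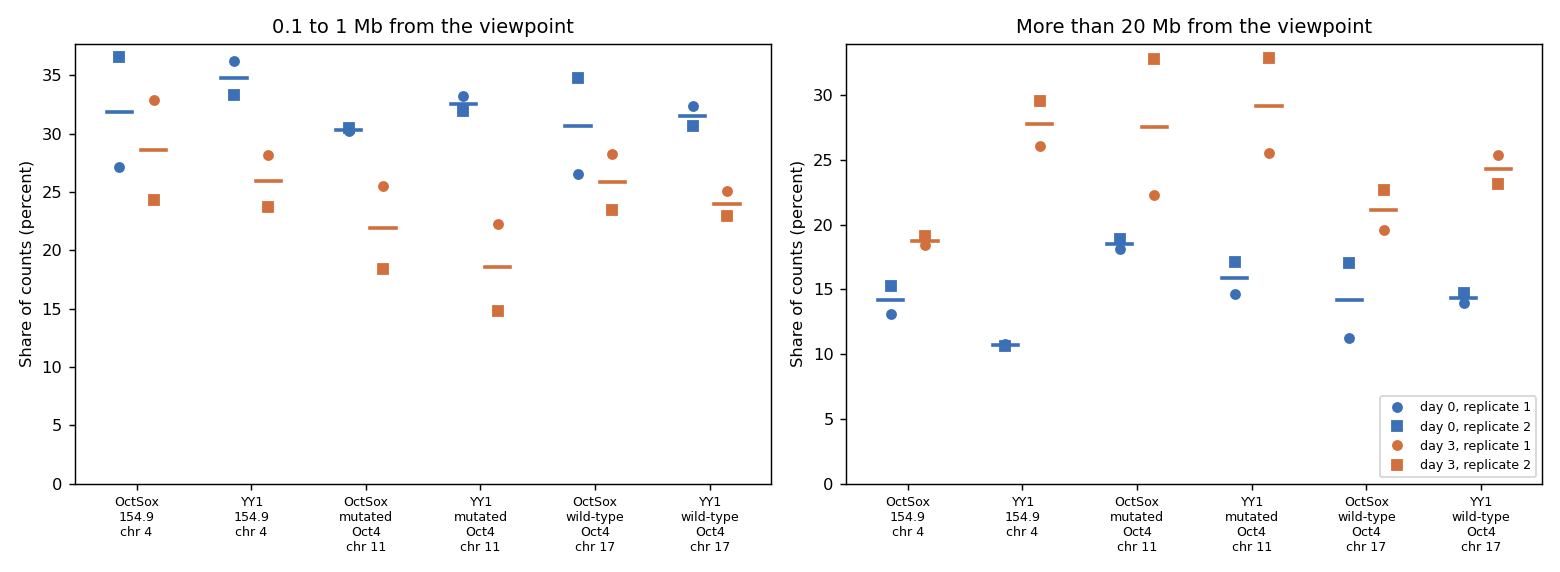
Share of counts (percent) at 0.1 to 1 Mb and at more than 20 Mb from the viewpoint for each library, by line and viewpoint; points are libraries and horizontal bars are means of 2 replicates. Beyond 20 Mb both day 3 libraries lie above both day 0 libraries in all 6 combinations.

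Close to the wild-type Oct4 allele, the fragment 35641102 to 35643148 on chromosome 17, which adjoins the viewpoint fragment, took a larger share of all counts at day 3 in both lines. In the OctSox line it held 0.0775% (95% Wilson interval 0.0694 to 0.0865) and 0.0343% (0.0166 to 0.0709) at day 0, and 1.86% (1.81 to 1.91) and 4.7% (4.41 to 5.01) at day 3. In the YY1 line it held 0.338% (0.319 to 0.358) and 0.0543% (0.0389 to 0.0759) at day 0, and 10.4% (10.2 to 10.6) and 9.04% (8.61 to 9.49) at day 3. With nothing left out at the viewpoint, an alternative chosen after seeing the data, edgeR gave a log2 fold change of 5.44 ± 0.84 (SE) over both lines, with an adjusted p of 1.0e-07. For the OctSox line alone it was 4.90 ± 1.57 with an adjusted p of 0.705, and in the YY1 line alone 5.99 ± 0.43. As shares, the mean log2 change was 6.00 with an exact permutation p = 0.0556, the smallest that 36 arrangements allow, and an adjusted p = 0.417 over 10 fragments tested in this way. The viewpoint fragment itself also varied widely between libraries, from 1.72% of all counts in YY1 day 0 replicate 1 to 70.9% in OctSox day 0 replicate 1. Fragments touching the viewpoint can hold undigested or self-ligated product, and they were left out of the tests that follow.

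**Figure D3:**
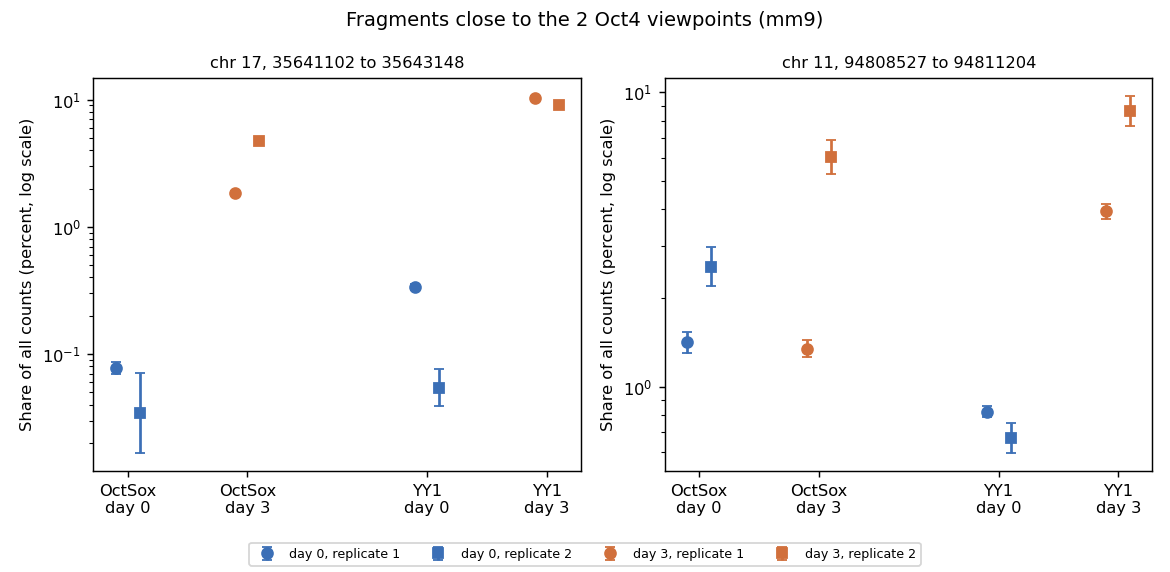
Share of all counts (percent, log scale) of the fragment adjoining the wild-type Oct4 viewpoint on chromosome 17 (35641102 to 35643148) and of a fragment near the mutated allele on chromosome 11 (94808527 to 94811204), for each library; bars are 95% Wilson intervals. On chromosome 17 the 4 day 3 libraries lie above the 4 day 0 libraries, and on chromosome 11 the days separate in the YY1 line but not in the OctSox line.

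Among the remaining fragments contacted by the wild-type Oct4 allele in the YY1 line, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2 of 716 tested, and both fell at day 3. The fragment 35666366 to 35668007 on chromosome 17, 25.3 kb from the viewpoint, had a log2 fold change of -1.42 ± 0.25 (SE) and an adjusted p of 2.0e-05. The fragment 35671799 to 35674740 had -1.15 ± 0.26 (SE) and an adjusted p of 0.00294, with shares of 2.74% and 2.92% at day 0 and 1.24% and 1.79% at day 3. In the OctSox line the same test called 0 of 731 fragments, with 17 at an unadjusted p under 0.05 and 0 by DESeq2, and the second of these fragments had a log2 fold change of -0.84 ± 1.06 (SE). Over both lines edgeR called 0 of 1270 fragments for the day, with 59 at an unadjusted p under 0.05 and 7 by DESeq2. Which YY1 fragments were called depended on the settings: within the YY1 line edgeR called 1 rise and 0 falls when scaled by total count and 7 rises and 0 falls with the distance trend removed. With nothing left out it called 2 rises, the viewpoint fragment and its neighbour from 35641102. The fragment from 35666366 stayed lower at day 3 in these settings without passing. The YY1 calls also depended on single libraries: there was 1 fall without either day 0 replicate, 41 rises and 71 falls (112 calls) without day 3 replicate 1 and 6 rises and 7 falls without day 3 replicate 2. DESeq2 called 4 in the YY1 line, all higher at day 3, and gave the fragment from 35666366 an adjusted p of 0.815. The OctSox count rose from 0 to 2 without day 0 replicate 1 or without day 3 replicate 1, and over both lines to 3 without OctSox day 0 replicate 2.

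Contacts of the mutated Oct4 allele rose at day 3 at one nearby fragment in the YY1 line. The fragment 94808527 to 94811204 on chromosome 11, 2.01 kb from the viewpoint fragment, held 0.822% (95% Wilson interval 0.788 to 0.857) and 0.667% (0.594 to 0.75) of all counts at day 0, and 3.95% (3.72 to 4.19) and 8.62% (7.66 to 9.69) at day 3. Its log2 fold change was 2.86 ± 0.20 (SE), with an adjusted p of 5.4e-39 by edgeR. In the OctSox line the shares were 1.42% and 2.56% at day 0 and 1.35% and 6.04% at day 3, with a log2 fold change of 0.99 ± 0.92 (SE) and an adjusted p of 0.997. The fragment from 94808527 held more counts than the viewpoint fragment in the YY1 day 3 libraries (1064 against 339 and 253 against 108). The same held in replicate 2 of both OctSox days, and the other libraries had fewer. Because the viewpoint position is inferred, undigested or self-ligated product at this fragment was not excluded. The difference between the lines was tested with an interaction term, which called 0 of 659 fragments at this viewpoint, with 36 at an unadjusted p under 0.05 and 0 by DESeq2. The other call in the YY1 line was 3686846 to 3689366 at 91123.8 kb, with 28 counts at day 3 against 0 at day 0 (edgeR adjusted p 0.00705). By counting error alone it was at least 93.6-fold higher at day 3, with a floor of 3 counts over the group. Of 428 fragments tested, edgeR thus called 2 and DESeq2 1. Without YY1 day 0 replicate 2 the fragment from 94808527 had an adjusted p of 1 and DESeq2 gave it 0.234. The fragment from 3686846 did not pass without either day 0 replicate. The count of calls was 1 without day 0 replicate 1, 0 without day 0 replicate 2, 64 without day 3 replicate 1 (17 rises, 47 falls) and 14 without day 3 replicate 2 (12 rises, 2 falls).

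In the OctSox line 3 of 210 fragments contacted by the mutated allele were called, all higher at day 3 and all far from it. They were 119247905 to 119250911, 76046580 to 76050286 and 85256152 to 85258451 on chromosome 11. They held 41, 38 and 34 counts at day 3, of which 39, 36 and 32 were in replicate 1, against 0 at day 0. By counting error alone they were at least 8.28-fold, 7.68-fold and 6.87-fold higher. Their edgeR adjusted p-values were 0.0125, 0.00725 and 0.00306. DESeq2 called 0, with an adjusted p of 0.995 for each, and the count was 1 without day 3 replicate 2 and 0 without any of the other 3 libraries. Over both lines the day test called 0 of 659 fragments, with 20 at an unadjusted p under 0.05 and 0 by DESeq2, and 1 without OctSox day 3 replicate 2, without YY1 day 0 replicate 1 or without YY1 day 3 replicate 2.

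For viewpoint 154.9, the deepest data, no single contact passed the test at day 3. In the YY1 line the smallest p belonged to the fragment 154987414 to 154988216 on chromosome 4, 34.9 kb away, with a log2 fold change of -2.47 ± 0.52 (SE) and an edgeR adjusted p of 0.639. The most contacted fragment of that line, 154966015 to 154967572, had shares of 2.98% and 4.65% at day 0 and 1.37% and 1.16% at day 3, a log2 fold change of -1.90 ± 0.49 (SE) and the same adjusted p. EdgeR called 0 of 6707 fragments, with 365 at an unadjusted p under 0.05 and 162 by DESeq2. In the OctSox line it called 0 of 4840, with 139 at an unadjusted p under 0.05 and 51 by DESeq2. The smallest edgeR p there belonged to 152354795 to 152357989, with 0 counts at day 3 against 433 at day 0 (adjusted p 0.826). By counting error alone this fragment was at least 143-fold lower at day 3, a bound that leaves out the spread between replicates. Over both lines edgeR called 0 of 9241, with 756 at an unadjusted p under 0.05 and 90 by DESeq2. Without YY1 day 3 replicate 1 the YY1 count was 276, with 217 rises and 59 falls, and without day 3 replicate 2 it was 114, with 24 rises and 90 falls. The OctSox count was 7 without day 3 replicate 1. Leaving out 1 library at a time over both lines gave 0 without YY1 day 3 replicate 2, 1 without YY1 day 0 replicate 1, 3 without YY1 day 0 replicate 2, 6 without YY1 day 3 replicate 1, 10 without OctSox day 0 replicate 2 and 4 without each of the other OctSox libraries.

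The lines differed most clearly in the counts of a single distant fragment at the mutated Oct4 viewpoint. The fragment 49209359 to 49209845 on chromosome 11, 45603.4 kb from the viewpoint, had 1124, 374, 354 and 65 counts in the 4 YY1 libraries and 0, 0, 3 and 1 in the 4 OctSox libraries. Its log2 difference, YY1 over OctSox, was 8.27 ± 1.29 (SE), with an adjusted p of 1.2e-07 by edgeR and of 9.1e-16 by DESeq2. It held between 0.431% and 2.21% of all counts in the YY1 libraries and at most 0.0295% in the OctSox libraries. Its direct neighbours held 0 counts in the YY1 libraries, except for 6 on the side of higher coordinates in day 3 replicate 2. The fragment 80690671 to 80697635 was lower in the YY1 line, with a log2 difference of -5.25 ± 1.38 (SE), an adjusted p of 0.0324 and 5, 2, 6 and 4 counts against 111, 93, 74 and 34. Another call, 5089052 to 5089727, came from 2 of the 4 OctSox libraries with 25 and 59 counts and was 0 in all others. By counting error alone it was at least 83.1-fold lower in the YY1 line, with a floor of 3 counts over the group. It passed without OctSox day 3 replicate 1 and without none of the other 7 libraries. EdgeR called these 3 of 659 fragments, and DESeq2 called 3, among them the fragments from 49209359 and 80690671 but not the one from 5089052. The first fragment had an adjusted p of 0.0572 without YY1 day 3 replicate 1, and the second had an adjusted p between 0.4 and 1 without any one of the 8 libraries. The count was 0 without YY1 day 3 replicate 1 and 1 without YY1 day 0 replicate 2 or YY1 day 3 replicate 2.

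At the other viewpoints no fragment distinguished the lines by edgeR. For viewpoint 154.9 it called 0 of 9241, with 775 at an unadjusted p under 0.05 and 58 by DESeq2, and leaving out single libraries gave between 1 (OctSox day 3 replicate 2) and 22 (OctSox day 0 replicate 2), with 7 without OctSox day 0 replicate 1 and 12 without YY1 day 3 replicate 1. The fragment with the smallest p there, 154986799 to 154987407 on chromosome 4, had a log2 difference of 2.12 ± 0.50 (SE) and an adjusted p of 0.577. For the wild-type Oct4 allele it called 0 of 1270, with 62 at an unadjusted p under 0.05 and 1 by DESeq2, and 2 without OctSox day 0 replicate 2. The fragment 29500553 to 29503613 on chromosome 17 had the smallest p, with 0 counts in the OctSox libraries and 145, 5, 38 and 0 in the YY1 libraries (adjusted p 0.645). Line and any batch of preparation cannot be told apart in this design, nor can line and allele at the mutated viewpoint.

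Changes between days were only weakly shared by the lines. Across fragments tested in both, Spearman's rho of the day effects was 0.1 (95% block-resampling interval 0.0571 to 0.142, 3740 fragments) for viewpoint 154.9, and 55.3% of fragments changed in the same direction. It was 0.0321 (-0.0483 to 0.333, 173 fragments) for the mutated Oct4 allele and -0.0418 (-0.123 to 0.076, 399 fragments) for the wild-type allele. Fragments are not independent replicates. For viewpoint 154.9, rho was 0.0128 without YY1 day 3 replicate 2 and 0.0139 without OctSox day 3 replicate 2, and neither of these 2 intervals excluded 0. It was 0.0248 (0.00338 to 0.0444) without a filter on low counts, 0.0552 (0.00855 to 0.0999) as Pearson's r and 0.182 (0.1 to 0.268) at a median count of 40. Without OctSox day 3 replicate 1 it was 0.0597 and without YY1 day 0 replicate 2 it was 0.0656. Tests of the difference in day effect between the lines called 3 of 9241 fragments for viewpoint 154.9, with 838 at an unadjusted p under 0.05 and 111 by DESeq2, and none of these 3 passed without YY1 day 3 replicate 2. For the wild-type allele they called 0 of 1270, with 58 at an unadjusted p under 0.05, 0 by DESeq2 and 1 without OctSox day 0 replicate 1.

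Replicates resembled each other near the viewpoints and much less far from them. Within 1 Mb, Spearman's rho across fragments between replicates had a median between 0.517 for the mutated Oct4 allele in the OctSox line and 0.943 for viewpoint 154.9 in the same line. Beyond 5 Mb the medians lay between -0.151 and 0.199 and were lower than within 1 Mb in all 6 combinations. Both sets held every fragment with a count in at least 1 library of its combination. Counts are sparser far from the viewpoints, which alone can lower rho, and this was not tested. Over all fragments with a mean count of at least 10 outside the viewpoint, the 12 pairs of replicates had a median rho of 0.324 (range 0.0557 to 0.43), and the 24 pairs of libraries from different days had a median of 0.294 (0.057 to 0.446). The common dispersion fitted by edgeR ranged from 0.528 to 2.62.

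Day 3 against day 0 was also given by the authors for the wild-type Oct4 allele and viewpoint 154.9. In the authors' deposited table for the wild-type allele in the OctSox line, 1 of 141 fragments passed an adjusted p of 0.05. This entry of the authors' deposited table was matched to 35641102 to 35643148 on chromosome 17, with a log2 fold change of 2.23 (day 3 over day 0) and an adjusted p of 0.0107. For the YY1 line an adjusted p was given for 102 of 136 fragments in the authors' deposited table, and 4 passed, all higher at day 3. Among them in the authors' deposited table was an entry with 2.86 and an adjusted p of 0.000163. It is assigned to the same fragment but could belong to the viewpoint fragment beside it. Another entry of the authors' deposited table, 35752778 to 35755901, had 2.53 and an adjusted p of 8.2e-05. For viewpoint 154.9 the authors' deposited table of the OctSox line gave an adjusted p for only 254 of 1690 fragments, and 0 passed 0.05. In the same authors' deposited table, 41 of the 1690 had an unadjusted p under 0.05. The authors' deposited table of the YY1 line gave an adjusted p for 2155 of 2536, and 11 passed, of which 10 were higher and 1 lower at day 3. Fragments with an empty adjusted p could not pass. Among the rises in the authors' deposited table, the fragment 119221439 to 119224149 on chromosome 4 had a log2 fold change of 4.38 (adjusted p 0.00246), 129237964 to 129246532 had 3.04 (0.0055) and 154057284 to 154060065, 892 kb from the viewpoint, had 2.90 (0.00983). The fall was at 147627120 to 147634461, with -3.95 (0.00671) in the authors' deposited table. Fold changes in the authors' deposited tables and those refitted here had a Spearman's rho of 0.965, 0.924, 0.925 and 0.89 across fragments for OctSox 154.9, OctSox wild-type, YY1 154.9 and YY1 wild-type.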

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

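The tests of the fragment beside the wild-type Oct4 viewpoint were chosen after its rise was seen.

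At viewpoint 154.9 the day effect differed between the lines at 3 fragments of chromosome 4 by edgeR's interaction test, more positive in the YY1 line. The log2 difference was 13.16 for 99583914 to 99584493 (adjusted p 0.000501), 12.10 for 108801371 to 108804856 (adjusted p 0.00577) and 10.88 for 48262985 to 48265819 (adjusted p 5.2e-05). The YY1 day 3 replicates 1 and 2 disagreed widely, with 0 and 1917, 37 and 1883, and 0 and 4141 counts in that order of fragments. None of the 3 passed without YY1 day 3 replicate 2, with an adjusted p of 1 for each: the first fell to 0.33 and the last turned to -3.32, while the one from 108801371 kept a positive difference of 7.74, a fitted value that depends on the prior count because its OctSox day 3 libraries are at 0. The number of calls was 0 without OctSox day 3 replicate 1 or without YY1 day 0 replicate 1, 1 without YY1 day 0 replicate 2, 6 without OctSox day 0 replicate 1 and 10 without YY1 day 3 replicate 1.

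A rise lay in data outside the main tests, at the fragment 35641102 to 35643148 on chromosome 17 adjoining the wild-type Oct4 viewpoint, with a log2 fold change of 5.44 over both lines. Shallow day 3 libraries as the cause are argued against by the deeper replicate 1 libraries, where the smaller log2 ratio of shares between the 2 lines was 4.59. More uncut or self-ligated product at day 3 stays open: relative to the viewpoint fragment the count rose by a mean log2 of 3.80, by 5.09 in the OctSox line with all libraries separated, but by 2.50 in the YY1 line with day 0 replicate 1 at -2.34 and day 3 replicate 2 at -2.38. A change in chromatin next to Oct4 between the days may also contribute and was not tested separately.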

How the results depend on the processing

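The alternatives with nothing left out at the viewpoint in fits over both lines, without the 4 shallow libraries and with viewpoints as 1 unit were chosen after seeing the data; the others were planned. Each main result was paired with each of its alternatives other than single libraries. Of these pairs 106 were the same, 3 weaker, 5 stronger, 50 moved in count and 13 reversed. A count of calls that stayed at 0 was taken as the same, so the tally does not show how well calls held. Where pairs differed the cause was not tested, except that DESeq2 is a different test and windows and filters change the fragments tested. Whether replicate numbers pair the samples was checked by correlating, across fragments, the replicate difference at day 0 with that at day 3. The correlations lay between -0.0626 and 0.0959 over the combinations of line and viewpoint. With fitted common dispersions of 0.528 to 2.62, such low values cannot show whether the samples are paired.

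Counts of called fragments are given against the 3, 0, 0 (OctSox mutated, wild-type, 154.9) and 2, 2, 0 (YY1) reported. DESeq2 called 0, 0 and 51 in the OctSox line and 1, 4 and 162 in the YY1 line. No filter gave 0 (OctSox mutated), 0 (YY1 mutated), 0 (YY1 wild-type) and 20 (YY1 154.9). A median count of 40 gave 0, 1 and 0, and leaving out 50 kb 0, 1 and 0, for OctSox mutated, YY1 mutated and YY1 wild-type. Nothing left out gave 5 for OctSox mutated. Windows of 100 kb gave 1 and 3 for OctSox mutated and wild-type and 0 and 0 for YY1. Removing the distance trend gave 0, 31 (23 higher, 8 lower) and 7 (all higher) for OctSox mutated, YY1 mutated and YY1 wild-type, and the replicate block 0, 1 and 1. For YY1 wild-type, where the 2 reported calls are falls, DESeq2's size factors gave 1 fall, total counts 1 rise, nothing left out 2 rises (the viewpoint fragment and its neighbour) and DESeq2 itself 4 rises, while the fragment from 35666366 stayed lower in each. The block changed no other call except those below.

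Over both lines, the day test at 154.9 gave 90 by DESeq2, 4 without a filter and 2 in windows. At the mutated allele it gave 1 with DESeq2's size factors, 1 with a median of 40 and 2 in windows, and at the wild-type allele 3 with those factors, 7 by DESeq2, 1 in windows and 1 with nothing left out. The line test at 154.9 gave 58 by DESeq2, 2 without a filter and 4 with the replicate block, at the mutated allele 0 without a filter and 0 with a median of 40, and at the wild-type allele 1 by DESeq2. The interaction at 154.9 gave 6 with DESeq2's size factors, 111 by DESeq2, and 0 with a median of 40, in windows and with the replicate block, and at the mutated allele 1 in windows. The correlation of day effects at 154.9 was 0.0248 without a filter, 0.182 with a median of 40 and 0.0552 as Pearson's r; at the mutated allele it was -0.0367 without a filter, 0.118 in windows and 0.182 as Pearson's r, and at the wild-type allele 0.00911, -0.252 with a median of 40 and 0.126 in windows.

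The share beyond 20 Mb rose by 4.97 points with nothing left out (adjusted p 0.0547; adjusted p from 0.000107 to 0.278 over the alternatives) and by 10.2 with viewpoints as 1 unit, where the share at 0.1 to 1 Mb changed by -7.81; with 36 arrangements neither can pass. Counting fragments in place of counts left a rise of 4.64 points beyond 20 Mb, turned the change at 0.1 to 1 Mb to 1.0 points, took that up to 0.1 Mb to 0.546, 1 to 5 Mb to -1.42 (now past the threshold), 5 to 20 Mb to -4.76 and the slope to -0.112. Capped counts gave 0.976 up to 0.1 Mb, -2.02 at 5 to 20 Mb and -0.0229 for the slope. Nothing left out gave 10.3 up to 0.1 Mb and -2.72 at 5 to 20 Mb. Leaving out 50 kb gave a slope change of 0.082, past the threshold, and dropping the 4 shallow libraries 0.59 at 1 to 5 Mb.

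With each library left out, a lone library in a group being assumed to vary like the others, counts ranged from 0 to 7 (OctSox 154.9), 0 to 1 (OctSox mutated), 0 to 2 (OctSox wild-type), 0 to 276 (YY1 154.9), 0 to 64 (YY1 mutated) and 1 to 112 (YY1 wild-type). Over both lines they ranged from 0 to 10, 0 to 1 and 0 to 3 for day, 1 to 22, 0 to 2 and 0 to 2 for line, and 0 to 10, 0 to 0 and 0 to 1 for the interaction at 154.9, the mutated and the wild-type allele. Correlations ranged from 0.0128 to 0.104, -0.0389 to 0.0829 and -0.076 to 0.0749. Changes in share ranged from -4.46 to 0.0454 (up to 0.1 Mb), -8.6 to -7.03 (0.1 to 1 Mb), -0.881 to 0.163 (1 to 5 Mb), -0.569 to 1.01 (5 to 20 Mb) and 9.28 to 11.04 (beyond 20 Mb), and the slope from 0.0292 to 0.0755. For named fragments, 305 results under other settings were the same, 33 weaker, 32 stronger and 7 moved; with single libraries left out 254 were the same, 38 weaker, 31 stronger and 2 reversed. The reversals were in the interaction on chromosome 4 without YY1 day 3 replicate 2: -3.32 for 48262985 (range -3.32 to 16.4) and -1.35 for 107885989 (range -1.35 to 17.2). Depth was lowest at the mutated Oct4 allele, where the shallowest libraries hold 2935 and 3395 counts.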

Other observations

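The tests of capped counts, of shallow libraries, of random ligation and of few reads, and the tests of the share held by the viewpoint, were chosen after the results they concern were seen.

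Outside the comparisons between fragments, the viewpoint and its neighbours took a larger part of the counts at day 3, by a mean of 14.9 percentage points over the 6 combinations (exact permutation p = 0.0484, unadjusted, 1 of 4 such tests). The rise was 23.8 points for viewpoint 154.9 (exact permutation p = 0.111), 10.5 points for the Oct4 alleles together (p = 0.281 by the same exact test) and 10.2 points without the 4 shallow libraries (p = 0.249 by the same exact test). In OctSox day 0 replicate 1 of the wild-type allele that share was 72.5%, and in replicate 2 of the same group 8.72%. The mutated allele showed no rise, with 13.3% and 1.63% at day 0 and 5.13% and 5.39% at day 3 in the OctSox line and 3.06% and 2.47% against 1.96% and 3.92% in the YY1 line. The rise at the Oct4 alleles came mostly from the wild-type allele in the YY1 line, with 2.38% and 2.61% at day 0 and 24.5% and 56.5% at day 3.

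The rise in the share of counts beyond 20 Mb at day 3 was weighed against 3 explanations. A few fragments with very high counts stay open, though the mean rise was 10.4 points with counts capped. The cap was set over the whole library and also lowers high counts near the viewpoint, so it cannot decide for fragments beyond 20 Mb. With fragments counted in place of counts, where high counts carry no extra weight, a smaller rise of 4.64 points remained (adjusted p = 0.0494, exact permutation). Shallow day 3 libraries are argued against, since the mean rise was 8.6 points without day 3 replicate 2 of the Oct4 alleles. OctSox day 0 replicate 2 of the mutated allele, with 6337 counts, was kept. More randomly joined ligation products at day 3 stay open: the log2 ratio of the share up to 0.1 Mb to that at 0.1 to 1 Mb changed by 0.38 (exact permutation p = 0.179), neither near 0 nor past the threshold. This test replaced a first one whose result had been seen, in which mixing day 0 profiles with evenly spread counts missed the change at 0.1 to 1 Mb by -2.12 ± 0.879 points (SE over 6 combinations), beyond its bound of 2 SE, and the other nearer bands by 2.41 ± 1.78, 0.229 ± 0.589 and -0.516 ± 0.939; by its own bound it argued against random joining, but it assumes an even profile. A looser chromosome at day 3 may therefore not be told from noisier ligation, and a template shared by the 3 viewpoints could move all of them together.

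The signal at 49209359 to 49209845 on chromosome 11, seen in the YY1 line and hardly in the OctSox line, was weighed against 2 explanations. A rearrangement or second insertion near it in the YY1 line is argued against by the surrounding fragments: within 1 Mb on either side their mean share differed by -0.112 percentage points, YY1 minus OctSox, with ranges of 0.206% to 0.886% and 0.289% to 1.36%. Few reads are argued against by a lowest YY1 count of 65. The signal hardly reached the direct neighbours, which held 0 counts in the YY1 libraries apart from 6 on the side of higher coordinates in day 3 replicate 2. A mispriming site or a sequence difference at this single short fragment was not tested, and the mutated site that distinguishes the lines cannot be separated from other differences between them.

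Other divisions of the 8 libraries of a viewpoint into 4 and 4 were used to ask whether chance gives as many calls. For the line comparison of the mutated Oct4 allele, 1 of 35 divisions, the real one, gave as many as 3 calls and the highest other gave 1. That share is under 0.05 but is not adjusted for the 6 comparisons, 1 of the 3 calls has libraries that overlap between the lines, and the count is 0 without YY1 day 3 replicate 1, so chance is not firmly excluded. For the other 5 comparisons the real count was 0, which all 35 divisions reach by construction, so nothing about chance follows. The highest other counts there were 24 (154.9, day), 30 (154.9, line), 3 (mutated allele, day), 5 (wild-type allele, day) and 4 (wild-type allele, line). The 3 is the division by line and the 4 the division by day, each fitted without a covariate because the division equals the covariate. At viewpoint 154.9 the division by line gave 17 calls and that by day 3 when fitted in this way. The divisions with 24 and 30 calls each differ from the line division by 1 exchanged library, and what sets them apart was not tested.

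That replicates agree less in rank beyond 5 Mb than within 1 Mb, as seen in all 6 combinations, was predicted before its result was seen. Its weighing against technical explanations was set aside in favour of the rise beyond 20 Mb after both were known. Sparse counts far from a viewpoint can lower rank agreement by themselves, so the met prediction says little about contacts.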
